A study of Homo sapiens with 23 samples.

How the data were processed

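Messenger RNA was sequenced from 23 xenograft tumors. The tumors grew from 2 human non-small cell lung cancer lines, H358 and H596, each carrying a doxycycline-inducible form of NRF2 with the activating change E79Q. NRF2 is the transcription factor encoded by NFE2L2 that drives genes for antioxidant defence. Per the labels' protocols, about 5 M cells were placed under the skin of a mouse, and mice of the DOX groups drank water with 2 mg/ml doxycycline and 1% sucrose once the tumor reached about 150 mm3. Tumors were collected 8 weeks later or at signs of distress, and polyA RNA was enriched. Each replicate came from a different mouse. The labels do not say whether the mice without doxycycline drank sucrose, and no tumor of a line without the inducible gene was analysed here, so doxycycline and NRF2 induction always came together.

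The deposited values were estimated counts per gene symbol and TPM values per gene symbol, both as Salmon gives them, per the submitters' processing notes. The notes also name STAR, FastQC, Picard, GRCh38 and hg38. Versions, the annotation release, the strand setting and any removal of mouse reads are not given in the sources used here. The authors' estimated count table held 59427 gene symbols, 34391 of them with at least 1 count. Library totals ran from 17.1 to 26.4 M estimated counts. The deposited TPM table was used for 1 alternative test and not for the main results.

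Estimated counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr on the 4 groups with a minimum count of 10, which left 18838 genes holding 99.9% of the counts. Libraries were scaled by the trimmed mean of M values (TMM). All 23 libraries entered 1 edgeR quasi-likelihood fit with a mean per group, in R 4.3.3 with edgeR 4.0.16. The common biological coefficient of variation was 0.400, with 19 residual degrees of freedom. The contrasts were DOX against NO-DOX in H358, the same in H596, and the difference between those changes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of single genes come from this edgeR test unless another tool is named. Fold changes are log2 values with their standard error (SE), and levels are TMM-normalized CPM as mean ± SD.

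For the group comparisons, 30 gene lists were fixed before the data were examined. The lists cover NRF2 target groups, lung and squamous differentiation, tumor state, and 7 sets of markers of host or other cell types. A list needed 3 tested members, so 29 lists were tested and the blood cell list, with too few measured members, was not. Lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over both lines. Camera with an estimated correlation and fry were run beside it. After the data were seen, the mean log2 CPM of each list was also compared between groups with an exact two-sided permutation test within each line, adjusted over the 58 tests.

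The genes named were set by a rule fixed before the data were examined. It takes NFE2L2, NQO1, TP63, SOX2, KRT5 and NKX2-1 always. It takes the 5 largest rises and the 5 largest falls per line among called genes with a mean log2 CPM of at least 1 and no overlap between the groups. It takes up to 2 called members of each of 8 primary lists and 1 of every other list, by size of change among those with a mean log2 CPM of at least 0. For the difference between lines it takes the 5 largest positive and the 5 largest negative values among called genes with a mean log2 CPM of at least 1 in both lines. Some genes that the rule takes are not reported here. Other genes named were chosen after their values were seen, as further members of the fixed lists or of a stated count. Gene positions are from GENCODE release 29 on GRCh38, matched by symbol: 18053 of the 18838 tested symbols and all 64 genes taken by the rule had a match.

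The fit was tested on simulated data with known changes in 200 of 18838 genes per line. At a log2 change of 1, 43% of changed genes were recovered in H358 and 42% in H596. At a log2 change of 2, 80% and 87% were recovered. For the difference between lines, 15% were recovered at a log2 change of 1, and between 62% and 67% at 2. At most 7.19% of the calls were false. The raised list was called in both lines and 0 other lists were. The simulated genes varied independently, so this could not show false list calls that come from correlated genes. The removal of a length and GC trend was tested in the same way on the H358 comparison: it lowered false calls from 1095 to 5 and recovered 79.5% of the changed genes, against 82.0% without it. The simulated trend followed the same transcript lengths that the removal fits. This test therefore cannot show whether a trend in the real data is technical.

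Alternatives fixed before the data were examined were median-of-ratios size factors, no filter, a filter of CPM of at least 1 in 5 libraries, each line fitted alone, the number that opens each sample title as a covariate or a subset, a replicate block, a stromal marker covariate, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), a fold threshold, and leaving out each library. The number in the titles is 7 or 9, its meaning is not stated, and it is balanced over the groups: each group has 3 of each, except H596 NO-DOX with 3 and 2. Alternatives added after the data were seen were the removal of a trend in transcript length and GC content, sample quality weights in limma-voom, and leaving out 3 libraries together (H358 DOX replicates 4 and 5 and H596 NO-DOX replicate 1). No pair of libraries agreed within sampling noise, so each was counted once. Intervals from counts cover counting error only.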

Results

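RNA was measured in 23 tumors in 4 groups: 6 H358 tumors with doxycycline (DOX), 6 without (NO-DOX), 6 H596 tumors with DOX and 5 without. H358 and H596 are established human lung cancer lines, H358 from an adenocarcinoma subtype and H596 from an adenosquamous tumor. Both lines carry an NRF2 E79Q gene made to be induced by DOX, and its induction was not measured apart from the cell's own NFE2L2. Totals ran from 18.1 to 26.4 M counts in H358 DOX, from 17.2 to 23.8 M in H358 NO-DOX, from 18.3 to 21.3 M in H596 DOX and from 17.1 to 23.9 M in H596 NO-DOX. Replicates of a group correlated across genes with r of at least 0.898, the lowest value being in H596 NO-DOX. Replicate 1 of H596 NO-DOX stood apart, with a TMM factor of 0.516 and 34.5% of its counts in its 50 most counted genes.

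The genes fixed in advance were examined first. NQO1, a quinone reductase and classic NRF2 target (chromosome 16, 69706996 to 69726951), rose from 142 ± 21.5 to 683 ± 120 CPM in H358 (log2 change 2.27, SE 0.27, adjusted p = 2.62e-06) and from 147 ± 85.4 to 536 ± 130 CPM in H596 (1.87, SE 0.28, adjusted p = 0.000258). Every DOX tumor lay above every NO-DOX tumor of its line. NFE2L2 itself (chromosome 2, 177227595 to 177392697) did not pass the test: 52.8 ± 11.8 CPM without and 68.2 ± 18.2 CPM with DOX in H358 (0.37, SE 0.26, adjusted p = 0.403), and 1.3e+02 ± 62.7 CPM without and 188 ± 31.8 CPM with DOX in H596 (0.51, from 0.27 to 0.73 without any 1 library, SE 0.27, adjusted p = 0.266). The deposited gene-level values do not separate the introduced gene from the cell's own copy. TP63, the master regulator of squamous cells (chromosome 3, 189631416 to 189897279), changed by 0.64 in H358 (SE 0.32, adjusted p = 0.225) and by 0.32 in H596 (from 0.16 to 0.45 without any 1 library, SE 0.34, adjusted p = 0.592), and SOX2 (chromosome 3, 181711924 to 181714436) by -0.91 (SE 0.46, adjusted p = 0.217) and 0.29 (from -0.08 to 1.15 without any 1 library, SE 0.50, adjusted p = 0.768), none past the threshold. KRT5, a basal keratin (chromosome 12, 52514575 to 52520687), fell in H358 from 150 ± 173 to 3.41 ± 3.40 CPM (-5.45, SE 0.71, adjusted p = 1.03e-05). In H596, where it is abundant, it was 4413 ± 1173 CPM without and 4331 ± 899 CPM with DOX (-0.03, from -0.12 to 0.09 without any 1 library, SE 0.61). NKX2-1, the lung lineage factor (chromosome 14, 36516392 to 36521149), fell in H358 from 191 ± 59.5 to 108 ± 24.4 CPM (-0.82, SE 0.21, adjusted p = 0.0131). Among libraries with title number 7 the change of NKX2-1 in H358 was -1.26 (adjusted p = 0.0136), and among libraries with title number 9 it was -0.29 (adjusted p = 0.813). In H596 both groups held 1 count of NKX2-1, so no fold is given.

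**Figure D1:**
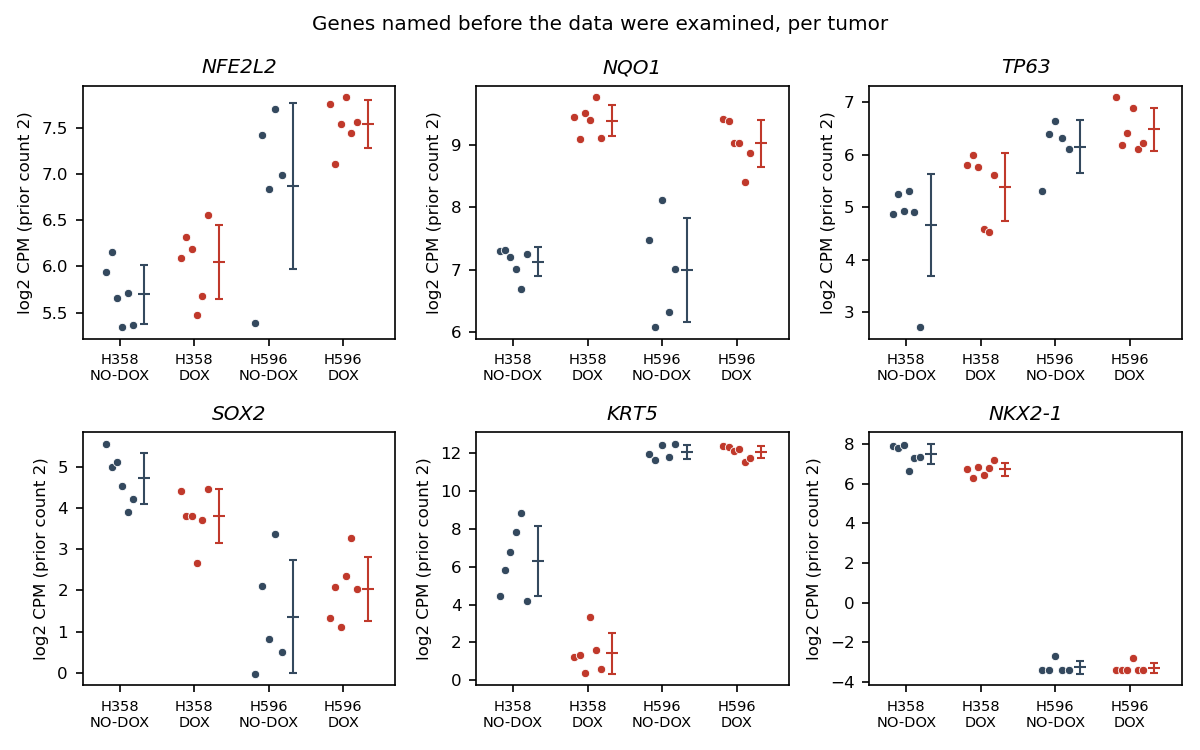
Level of NFE2L2, NQO1, TP63, SOX2, KRT5 and NKX2-1 in each tumor, as log2 CPM with a prior count of 2. Points are tumors (6, 6, 5 and 6 from left to right), and the bar beside each group is the mean with the SD. NQO1 is higher in every DOX tumor of both lines, and KRT5 is lower in every DOX tumor of H358.

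The first comparison asks what changed with DOX in H358 tumors. The groups of NRF2 target genes rose together, while genes of the lung alveolar lineage fell. Interferon response and antigen presentation genes fell too, though these list calls were lost with an estimated correlation (adjusted p = 0.125 and 0.241). Of 18838 genes tested, 2181 were called, 1041 higher and 1140 lower with DOX. The tetraspanin TSPAN7 had 9981 counts over the 6 DOX tumors and 1 count over the 6 NO-DOX tumors, a ratio of 10778 with a 95% counting interval of 1934 to 425767. CYP4F11, a fatty acid hydroxylase, rose from 0.056 ± 0.058 to 61.1 ± 24.1 CPM (9.88, SE 0.49, adjusted p = 4.20e-13), and AKR1B10, an aldo-keto reductase, from 0.490 ± 0.304 to 342 ± 140 CPM (9.45, SE 0.46, adjusted p = 4.20e-13). The size of the CYP4F11 rise rests on a NO-DOX level near 0 (from 9.64 to 10.4 without any 1 library). SPANXA2 and SPANXB1, testis antigens on chromosome X, rose by 9.82 (SE 0.86) and 8.67 (SE 0.98), and near-identical copies of these genes can share their reads. Among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest falls were KRT5, given above, then SLC34A2, the alveolar phosphate carrier (-5.37, SE 0.47, adjusted p = 1.02e-07), SCGB3A2, a secretoglobin of airway cells (-4.05, SE 0.46), STEAP4, a metalloreductase (-3.98, SE 0.54), and PLXNC1, a semaphorin receptor (-3.80, SE 0.49). The rises given here are the largest of the same set.

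The antioxidant and detoxification lists moved the most in H358. In the glutathione and thioredoxin list, 12 of 14 measured genes rose and 0 fell (13 rose when adjusted over the list alone), with a median log2 change of 2.19 (camera adjusted p = 4.28e-26). The selenium-dependent peroxidase GPX2 rose by 6.07 (SE 0.41) and SLC7A11, the cystine importer, by 4.59 (SE 0.30). GCLM, a subunit of the glutathione-making ligase, rose by 3.84 (SE 0.23) and the thioredoxin reductase TXNRD1 by 3.33 (SE 0.25). In the detoxification and export list all 20 genes rose (20 when adjusted over the list alone), with a median of 3.78 (camera adjusted p = 1.06e-41). CYP4F11 and CYP4F3, the AKR1C genes and UGT1A6 belong to families of similar genes that can share reads. In the NADPH and pentose phosphate list 6 of 7 rose (7 when adjusted over the list alone), with a median of 2.13 (camera adjusted p = 9.28e-15), among them PGD, an enzyme of the pentose phosphate path (3.05, SE 0.15, adjusted p = 4.20e-13). In the heme and iron list 7 of 8 rose, with a median of 1.13 (camera adjusted p = 7.24e-07), among them the ferritin light chain FTL (2.29, SE 0.33, adjusted p = 3.88e-05). Of 12 NRF2 pathway regulators 6 rose, with a median of 0.56 (camera adjusted p = 1.09e-06). OSGIN1 rose by 3.69 (SE 0.30) and TRIM16L by 2.11 (SE 0.16), and KEAP1, which marks NRF2 for degradation, rose by 0.74. The regulators' call was lost with an estimated correlation (adjusted p = 0.0610).

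Differentiation genes of H358 fell in the alveolar direction and changed both ways in the squamous one. In the alveolar and adenocarcinoma list 8 of 16 measured genes fell and 1 rose (9 and 1 when adjusted over the list alone), with a median of -1.13 (camera adjusted p = 4.79e-05). Besides SLC34A2 and NKX2-1, the fall took in the lamellar body protein LAMP3 (-2.70, SE 0.44, adjusted p = 0.000192) and the aspartic protease NAPSA (-2.61, SE 0.56, adjusted p = 0.00282), while CEBPA, a myeloid and lung transcription factor, rose by 2.47 (SE 0.39). In the airway secretory list 2 of 18 fell, SCGB3A2 and the immunoglobulin receptor PIGR (-3.24, SE 0.92, adjusted p = 0.0249), with a list median of -0.64 (camera adjusted p = 0.00518, and adjusted p = 0.420 with an estimated correlation). PIGR lost its call without any 1 of 5 libraries. In the ciliated cell list 2 of 11 fell (5 when adjusted over the list alone), including the ciliogenesis factor FOXJ1 (-2.30, SE 0.67, adjusted p = 0.0260), with a median of -0.70 (camera adjusted p = 0.00518, and adjusted p = 0.0590 with an estimated correlation). The list's call ended without H358 NO-DOX replicate 6 (adjusted p = 0.0572), and FOXJ1's ended without any 1 of 6 libraries. Of 29 basal and squamous genes 2 rose and 4 fell (camera adjusted p = 0.981, with a median of -0.04, from -0.31 to 0.12 without any 1 library, below 0 and the test's direction above it). Those that fell included KRT5 and DSG3, a desmosomal cadherin (-3.31, SE 0.62, adjusted p = 0.000862). The DSG3 call held without any 1 library (from -3.56 to -2.29) but was lost in 5 of the other alternatives. Of 29 cornification genes 1 rose, the mucosal keratin KRT4 (1.81, SE 0.51, adjusted p = 0.0220), and 2 fell, among them ECM1 (-1.46, SE 0.37, adjusted p = 0.0112), with a list median of -0.02 (from -0.69 to 0.12 without any 1 library, camera adjusted p = 0.802). The list was barely expressed in H358, with a mean log2 CPM of -0.30 without and -0.47 with DOX. Both of the named calls ended when 1 library was left out, KRT4 without H358 NO-DOX replicate 5 (adjusted p = 0.0516) and ECM1 without H358 NO-DOX replicate 4 (-0.83, adjusted p = 0.0516).

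**Figure D2:**
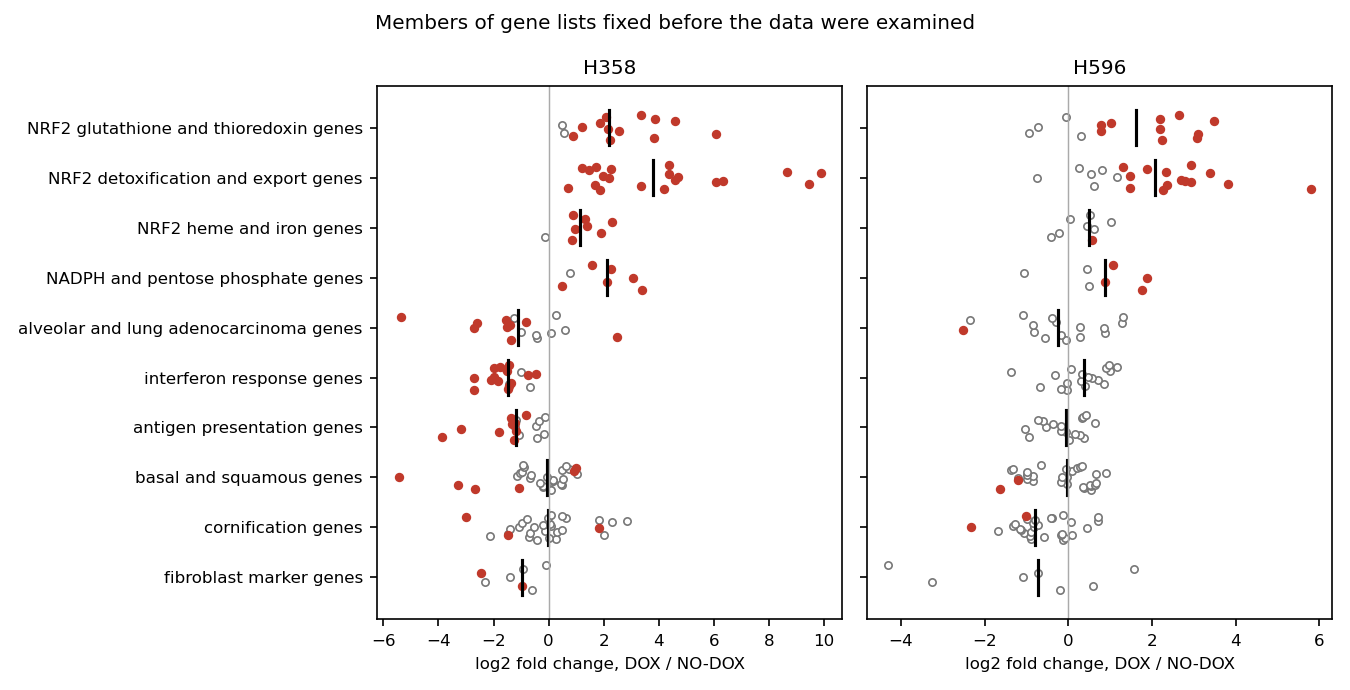
Log2 fold change of the tested members of 10 gene lists in H358 (left) and H596 (right), DOX over NO-DOX. Filled red points passed an adjusted p of 0.05, open points did not, and the black bar is the list's median. In the detoxification list 20 of 20 members are filled in H358 and 14 of 20 in H596, and in the interferon list 15 of 18 are filled in H358 and 0 in H596.

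Interferon response, antigen presentation and fibroblast marker genes also fell in H358, while the other host marker lists were not called. In the interferon response list 15 of 18 genes fell and 0 rose (16 when adjusted over the list alone), with a median of -1.49 (camera adjusted p = 5.74e-11, and adjusted p = 0.125 with an estimated correlation). IFIT2, an interferon-induced RNA-binding protein, fell by 2.72 on the log2 scale (SE 0.55, adjusted p = 0.00167). The list mean was lower in each of the 6 DOX tumors than in all 6 NO-DOX tumors (mean log2 CPM 5.79 ± 0.37 against 7.33 ± 0.46, exact permutation p = 0.00216, the smallest these splits can give, adjusted p = 0.00785). In the antigen presentation list 9 of 17 fell and 0 rose (11 fell when adjusted over the list alone), with a median of -1.18 (camera adjusted p = 2.04e-06, and adjusted p = 0.241 with an estimated correlation). They included the class II chaperone CD74 (-3.87, SE 0.72, adjusted p = 0.000853), HLA-B (-1.80, SE 0.41, adjusted p = 0.00467) and B2M (-1.27, SE 0.32, adjusted p = 0.00933). The lists of markers of host or other cell types were counted on human gene symbols, so reads of the tumor cells can enter them. For instance, the adipocyte list mean without DOX was -0.59 log2 CPM in H358 and 4.32 in H596. Of these markers, 2 of 7 fibroblast genes fell, LUM, a matrix proteoglycan (-2.46, SE 0.43, adjusted p = 0.000436), and COL1A1 (-0.96, SE 0.19). The fibroblast list median was -0.96 (3 fell when adjusted over the list alone, camera adjusted p = 0.00224, and adjusted p = 0.0146 with an estimated correlation). Of 6 endothelial genes 2 fell, KDR (-1.95, SE 0.32, adjusted p = 0.000218) and PECAM1, and EGFL7 rose (1.39, camera adjusted p = 0.808 for the list). Of 5 macrophage and leukocyte genes CD14 fell (-1.71, SE 0.33, adjusted p = 0.00104) and CD68 rose (1.40, SE 0.39, adjusted p = 0.0189), with camera adjusted p = 0.808. Skeletal muscle (camera adjusted p = 0.479), adipocyte (0.981, with the median of -0.02, from -0.15 to 0.08 without any 1 library, and the test's direction on opposite sides of 0) and skin appendage lists (0.879) had 0 called members in H358.

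Other lists in H358 held few called members. Of 17 amino acid response genes 4 rose (5 when adjusted over the list alone), among them SLC3A2, the partner chain of SLC7A11 (1.35, SE 0.25, adjusted p = 0.000776), with a median of 0.47 (camera adjusted p = 0.00219, and adjusted p = 0.0987 with an estimated correlation). Of 22 proliferation genes 2 rose, the mitotic kinase PLK1 (0.71, SE 0.17, adjusted p = 0.00815) and MCM5, with a median of 0.32 (camera adjusted p = 0.000743, and adjusted p = 0.528 with an estimated correlation and 0.0697 by fry). The mean of the proliferation list did not pass the exact permutation test (adjusted p = 0.188). Of 10 neuroendocrine and tuft genes 2 rose, UCHL1, a neuronal ubiquitin hydrolase (3.24, SE 0.34, adjusted p = 4.16e-07), and CHGA. The list was not called by camera (adjusted p = 0.195), but its mean was higher in all 6 DOX tumors than in every NO-DOX tumor (by 0.60 log2 CPM, exact permutation adjusted p = 0.00785), and fry passed (adjusted p = 0.000524). The median log2 change of its members was 0.04 (from -0.08 to 0.23 without any 1 library), so few of them carried the mean. ELOVL6, a fatty acid elongase, rose by 0.67 (SE 0.22, adjusted p = 0.0437), a call that ended without any 1 of 13 libraries, and was 1 of 18 lipid synthesis genes called (camera adjusted p = 0.204). ST14 was the 1 epithelial junction gene of 17 to fall (-0.73, SE 0.22, adjusted p = 0.0351), and its call ended without any 1 of 9 libraries (camera adjusted p = 0.754 for the list). The cytokine IL1B was the 1 inflammatory gene of 17 to rise (3.87, SE 0.96, adjusted p = 0.00924), in a list with a median of -0.32 (from -0.61 to -0.15 without any 1 library), a mean of 0.10 and camera adjusted p = 0.861. Lists with 0 called members were mesenchymal transition (camera adjusted p = 0.122), hypoxia (0.309), Notch (0.746), gastrointestinal and hepatic (0.746) and mitochondrially encoded genes (0.891, with the median of -0.13, from -0.26 to 0.09 without any 1 library, and the test's direction on opposite sides of 0). On H358 as a whole, camera called 13 of 29 lists, 7 higher and 6 lower, and 6 calls held with an estimated correlation. By the exact permutation test of list means 13 lists passed, 12 of them among camera's 13. The gene count ran from 1553 to 2854 when single libraries were left out. It was 1097 among tumors with title number 7 and 294 with title number 9, and 1121 with an absolute log2 change of at least 1. Without TMM scaling, on log2(TPM + 1), limma called 1986 genes with 26.4% of them higher, against 47.7% in the edgeR test, and the median change of all genes was -0.17 against -0.04.

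**Figure D3:**
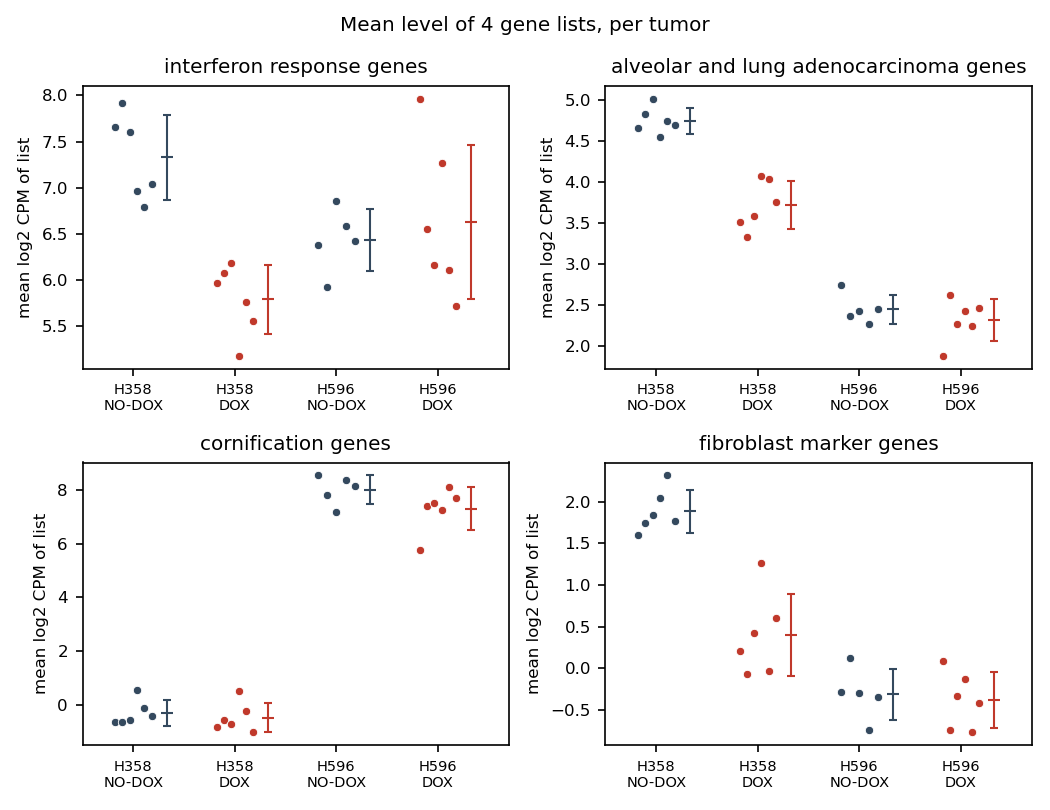
Mean log2 CPM of the interferon response, alveolar, cornification and fibroblast marker lists in each tumor. Points are tumors, and the bar beside each group is the mean with the SD. The interferon, alveolar and fibroblast means of the 6 H358 DOX tumors all lie below those of the 6 H358 NO-DOX tumors, and the other groups overlap with their counterparts.

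The same question was asked in H596. The glutathione, detoxification and NADPH lists rose here too, with fewer called members. The NRF2 regulators were called by camera but not with an estimated correlation (adjusted p = 0.0810), and the heme and iron list was not called by camera (adjusted p = 0.0831) but passed fry (adjusted p = 0.0237). Of 18838 genes 653 were called, 381 higher and 272 lower. TSPAN7 rose from 0.509 ± 0.324 to 134 ± 37.3 CPM (7.98, SE 0.41, adjusted p = 3.84e-12). CES1, a carboxylesterase, rose by 6.69 (SE 0.74, adjusted p = 3.32e-06), the conjugate exporter ABCC2 by 5.80 (SE 0.36, adjusted p = 1.70e-10), the adhesion protein MDGA1 by 4.10 (SE 0.47) and AKR1B10 by 3.81 (SE 0.38), from 104 ± 28.9 to 1462 ± 275 CPM. The largest falls among called genes of that level without overlap included the receptor EPHB6 (-2.20, SE 0.38, adjusted p = 0.00649), SLCO4A1-AS1 (-2.17, SE 0.56), CARD18 (-2.14, SE 0.49) and SAP25 (-1.99, SE 0.39, adjusted p = 0.00570). SLCO4A1-AS1 lies antisense to a coding gene, and without a stated strand setting its reads cannot be told from that gene's. The calls of CARD18 and SLCO4A1-AS1 ended without H596 NO-DOX replicate 1 (adjusted p = 0.104 and 0.141), the latter also without 3 other libraries.

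In H596, 10 of 14 glutathione and thioredoxin genes rose and 0 fell, with a median of 1.61 (camera adjusted p = 5.24e-14); adjusted over the list alone, 10 rose and 1 fell. SLC7A11 rose by 3.47 (SE 0.31), GPX2 by 3.11 (SE 0.38) and GCLM by 3.08 (SE 0.24). Of 20 detoxification and export genes 14 rose (15 when adjusted over the list alone), with a median of 2.07 (camera adjusted p = 1.31e-24). Of 7 NADPH genes 4 rose (5 rose and 1 fell when adjusted over the list alone), with a median of 0.87 (camera adjusted p = 3.53e-06), among them PGD with 1.87 (SE 0.15, adjusted p = 2.02e-08). Of 12 NRF2 regulators 5 rose (7 when adjusted over the list alone), with a median of 0.54 (camera adjusted p = 4.32e-06, and adjusted p = 0.0810 with an estimated correlation). OSGIN1 rose by 1.88 (SE 0.30) and the small MAF partner MAFG by 1.65 (SE 0.27). Of 8 heme and iron genes 1 rose, the porphyrin carrier ABCB6 (0.56, SE 0.15, adjusted p = 0.0381), with a list median of 0.49 (3 rose when adjusted over the list alone); the gene's call ended without any 1 of 6 libraries. Camera called the list without H596 DOX replicate 5 (adjusted p = 0.0377), H596 NO-DOX replicate 1 (0.0182) or H596 NO-DOX replicate 5 (0.0214), and its mean did not pass the exact permutation test (adjusted p = 0.0925). UCHL1 rose by 2.10 (SE 0.36, adjusted p = 0.00124), the 1 called member of the neuroendocrine and tuft list (camera adjusted p = 0.423, with the median of -0.07, from -0.13 to 0.09 without any 1 library, and the test's direction on opposite sides of 0). The mean of that list was nonetheless higher in all 6 DOX tumors than in every NO-DOX tumor (by 0.49 log2 CPM, exact permutation adjusted p = 0.00785), and fry passed (adjusted p = 0.0114).

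Epithelial genes of H596 that fell did so at the edge of the test. Of 29 cornification genes 2 fell and 0 rose (5 fell when adjusted over the list alone), with a median of -0.79 (camera adjusted p = 7.46e-05, and adjusted p = 0.420 with an estimated correlation). They were LGALS7B, a galectin whose reads can be shared with its near-copy LGALS7 (-2.33, SE 0.57, adjusted p = 0.0245), and the crosslinking enzyme TGM1 (-1.01, SE 0.28, adjusted p = 0.0436). The list mean was 7.29 ± 0.80 with and 8.00 ± 0.54 log2 CPM without DOX (exact permutation p = 0.115). Of 29 basal and squamous genes KRT15 (-1.21, SE 0.31, adjusted p = 0.0328) and CALML3 (-1.64, SE 0.45, adjusted p = 0.0428) fell (camera adjusted p = 0.371). The simple epithelial keratins KRT8 (-1.13, SE 0.28, adjusted p = 0.0237) and KRT7 (-2.50, SE 0.61, adjusted p = 0.0248) fell as well, each the 1 called member of its list, with camera adjusted p = 0.00518 for the epithelial junction list (5 fell when adjusted over the list alone, adjusted p = 0.363 with an estimated correlation) and 0.692 for the alveolar list. Of 18 airway secretory genes 3 fell (5 fell and 1 rose when adjusted over the list alone), the mucin MUC5B and the trefoil factors TFF1 (-2.98, SE 0.82, adjusted p = 0.0498) and TFF3 (list median -1.04, camera adjusted p = 0.0216, and adjusted p = 0.528 with an estimated correlation). The ciliated gene TPPP3 (-1.82, SE 0.49, adjusted p = 0.0397), the Notch target HES4 (-1.18, SE 0.31, adjusted p = 0.0370) and the muscle troponin TNNI2 (-3.01, SE 0.82, adjusted p = 0.0416) also fell. Of 13 Notch genes 1 rose and HES4 alone fell, with a list median of 0.12 (from 0.01 to 0.44 without any 1 library). The lipid regulator SREBF1 rose by 0.63 (SE 0.18, adjusted p = 0.0436). The mesenchymal list had a median of 0.66 (camera adjusted p = 0.0454, and adjusted p = 0.685 with an estimated correlation). Without H596 NO-DOX replicate 1 the calls of LGALS7B, TGM1, CALML3, KRT8, KRT7, TFF1, HES4, TNNI2 and SREBF1 ended, with adjusted p-values from 0.105 for KRT8 to 0.362 for TFF1. Without that library the log2 changes were -1.32 for LGALS7B, -1.36 for KRT7, -1.46 for TFF1 and -1.32 for SAP25 (adjusted p = 0.0284), and the list medians were -0.43 for cornification and -0.44 for secretory genes (adjusted p = 0.000912 and 0.0610). The secretory list's call ended without any 1 of 3 libraries (at most adjusted p = 0.107, without H596 DOX replicate 1) and the mesenchymal list's without any 1 of 9 (at most 0.169, without H596 NO-DOX replicate 2). The epithelial junction list's call ended without H596 NO-DOX replicate 2 (median -0.13, adjusted p = 0.0666, from -0.23), and its median was -0.15, -0.40 and -0.35 without H596 DOX replicates 1, 5 and 6 and -0.36 without H596 NO-DOX replicate 3. KRT15 and TPPP3 lost theirs without H596 NO-DOX replicate 3 (adjusted p = 0.0891 and 0.175, with TPPP3 at -1.05), and each of these 11 genes lost its call without any 1 of at least 4 libraries.

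The mitochondrially encoded list had 0 of 13 called members in H596, a median of 0.57 and a camera adjusted p of 0.0153 (adjusted p = 0.744 with an estimated correlation, and at most 0.135 when 1 library was left out, H596 DOX replicate 3, with a median of 0.34). Mitochondrial genes took 6.44 ± 2.09% of counts in H596 DOX and 3.65 ± 1.48% in H596 NO-DOX (exact permutation p = 0.0346, adjusted p = 0.179 over 10 comparisons of library measures). Interferon response genes (median 0.37, from 0.02 to 0.49 without any 1 library, camera adjusted p = 0.735) and antigen presentation genes (median -0.05, from -0.31 to 0.28, camera adjusted p = 0.808) had 0 called members. Fibroblast (median -0.72, and above 0 at 0.04 without H596 NO-DOX replicate 5, camera adjusted p = 0.944), endothelial (0.808) and macrophage lists (0.805) also had 0. So did proliferation (camera adjusted p = 0.930), hypoxia (0.423), amino acid response (0.879, median 0.03, from -0.13 to 0.08 without any 1 library, and a test direction below 0), inflammatory cytokine (0.808), gastrointestinal and hepatic (0.329), adipocyte (0.770) and skin appendage genes (0.861). Besides TNNI2, myoglobin (MB) was the 1 other muscle marker of 5 to fall (-1.53, SE 0.35, adjusted p = 0.0172), with camera adjusted p = 0.599 for the list. The Notch list (camera adjusted p = 0.150), the lipid synthesis list (0.479) and the ciliated list (0.981, median 0.00, up to 0.44 without 1 library, and mean 0.64 against a test direction below 0) were not called. Camera called 9 of 29 lists in H596, 6 higher and 3 lower. Of these calls 3 held with an estimated correlation, those of the glutathione, detoxification and NADPH lists. Fry did not pass the cornification, secretory, epithelial junction, mesenchymal and mitochondrial calls (adjusted p from 0.0819 to 0.222), and the exact permutation test passed 5 lists, 4 of them among camera's 9.

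The number of called genes in H596 moved with single tumors. Leaving out H596 DOX replicates 1, 2, 3, 4 or 6 gave 328, 1173, 373, 325 or 364 genes, and leaving out H596 NO-DOX replicates 1, 2, 4 or 5 gave 287, 1229, 2069 or 432. Fitted without the H358 tumors, about 1.6e+02 genes were called, 87.3% of them higher. The share of rises also moved the other way, to 44.2% without H596 DOX replicate 2. The count was 178 with title number 7 and 19 with title number 9. DESeq2 called 1801 genes, and the stromal marker covariate gave 1202, with 49.7% of the 1202 higher. Without TMM scaling, on log2(TPM + 1), 95.1% of 711 calls were higher, against 58.3% in the edgeR test, and the median change of all genes was 0.31 against 0.01.

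The third comparison asks which changes differed between the lines, tested as the difference of the log2 changes (H358 minus H596). Of the 5 NRF2 lists the glutathione and NADPH lists rose more in H358, from lower NO-DOX means, also with an estimated correlation. The detoxification and the heme and iron lists (the latter 0.65, camera adjusted p = 0.0158) rose more in H358 and the interferon and alveolar lists fell more by camera alone, each lost with an estimated correlation (adjusted p = 0.0913, 0.259, 0.267 and 0.127), and the regulators did not pass (camera adjusted p = 0.296). A difference was called for 2187 genes, 1218 above 0 and 969 below. Among called genes with a mean log2 CPM of at least 1 in both lines, the largest positive differences were CYP4F11 (6.50, adjusted p = 2.12e-07), CYP4F3 (6.29, adjusted p = 1.33e-07), the hydrolase CMBL (5.86, adjusted p = 1.94e-05), AKR1B10 (5.64, adjusted p = 2.12e-07) and TSPAN7 (4.48, adjusted p = 0.00217). All 5 rose in both lines, and the NO-DOX level of the first 4 was lower in H358, for AKR1B10 0.490 CPM against 104 CPM. The TSPAN7 value rests on the 1 count of H358 NO-DOX, and on log2(TPM + 1) it was -0.17 (adjusted p = 0.726). The CYP4F11 value also rests on an H358 NO-DOX level near 0 (from 6.20 to 6.98 without any 1 library). The largest negative differences in that set were KRT5 (-5.42, adjusted p = 0.00116), the interferon-induced TRIM22 (-4.05, adjusted p = 0.00211), STEAP4 (-3.97, adjusted p = 0.00216), DSG3 (-3.82, adjusted p = 0.00731) and the interleukin receptor IL1R1 (-3.81, adjusted p = 1.88e-05). All 5 fell in H358 and none was called in H596. With the stromal marker covariate the KRT5 difference was -2.68 (adjusted p = 0.0172). The DSG3 difference held without any 1 library but lost its call in 5 of the other alternatives.

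As lists, the members' differences had a median of 1.67 for detoxification (camera adjusted p = 3.98e-07, and adjusted p = 0.0913 with an estimated correlation), 1.27 for NADPH (adjusted p = 1.28e-05) and 0.98 for glutathione genes (adjusted p = 6.04e-06), the last 2 with adjusted p = 0.0388 with an estimated correlation. Each of these lists had a lower NO-DOX mean in H358 than in H596. The NO-DOX means were 2.45 against 5.67 log2 CPM for detoxification, 6.25 against 6.91 for NADPH and 5.71 against 6.36 for glutathione genes. With DOX they were 6.34 against 7.77, 8.21 against 7.74 and 8.25 against 7.87. The interferon list differed by a median of -2.22 (camera adjusted p = 1.08e-06, and adjusted p = 0.267 with an estimated correlation), and the alveolar list by -0.53 (camera adjusted p = 0.0209, and adjusted p = 0.127 with an estimated correlation). The regulators (0.19, camera adjusted p = 0.296) and the basal and squamous genes (0.11, camera adjusted p = 0.576) did not differ past the threshold. SLC7A11, GCLM and NQO1 rose in both lines, and their differences of 1.11 (adjusted p = 0.0584), 0.76 (adjusted p = 0.0876) and 0.40 (adjusted p = 0.508) did not pass. ABCC2 rose more in H596 (-1.60, adjusted p = 0.0202).

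More rises than falls were called in both lines, a contrast that was not itself tested. Of 381 genes called higher in H596, 32.8% were called higher in H358 as well, where 5.53% of all tested genes were. Of 272 called lower in H596, 14 were called lower in both, where 16.5 would be by independence (one-sided Fisher's exact p = 2.44e-63 for the rises and 0.771 for the falls, across genes, which are not independent replicates). Of the shared rises 33 were on the 5 NRF2 lists, and most were on none of them. A difference between the lines was called for 29 in favour of H358 and for 5 in favour of H596, and for most it was not called. Their median log2 change was 2.11 in H358 and 1.84 in H596. Another 40 genes were called in opposite directions, 16 of them higher and 24 lower in H358, where 15.0 and 23.1 would be by independence. They include the aryl hydrocarbon receptor AHR (-1.31 in H358 and 0.94 in H596) and the endopeptidase MME (-0.94 and 2.23). Across all 18838 genes the log2 changes correlated with r = 0.06 and rho = -0.10. Across 11946 genes expressed in both lines they gave r = -0.01 and rho = -0.27, and across the 2655 genes called in either line r = 0.21. The count of genes that differ was 1335 without H358 DOX replicate 4, 1351 and 1357 without H358 NO-DOX replicates 1 and 2, 1385 without H596 DOX replicate 4, and 1408 and 3427 without H596 NO-DOX replicates 1 and 4. It was 573 with title number 7 and 16 with title number 9. On log2(TPM + 1), 9.54% of the calls were above 0, against 55.7% in the edgeR test, with a median difference of all genes of -0.51 against -0.09.

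**Figure D4:**
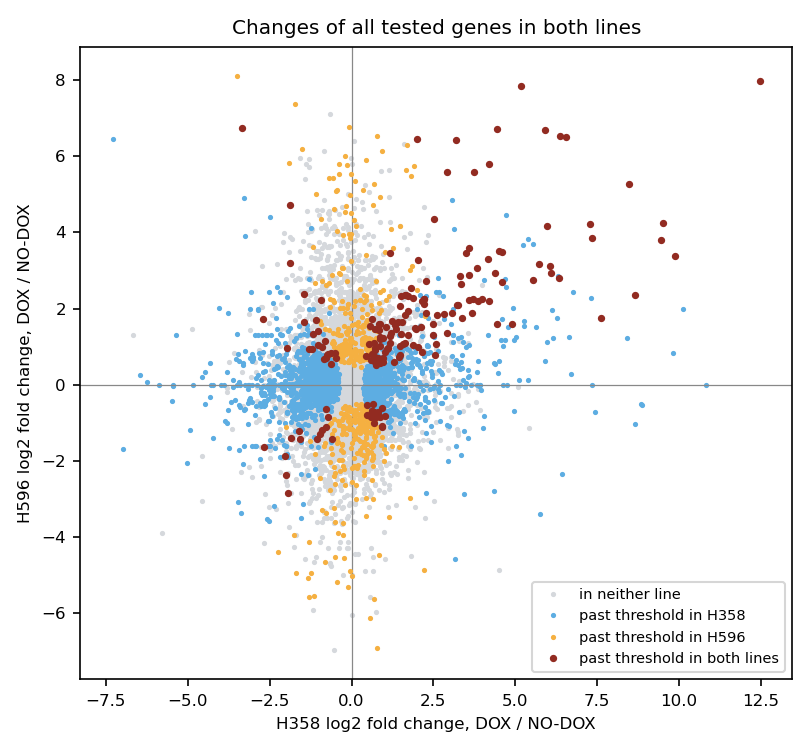
Log2 fold change of each of 18838 tested genes in H358 (horizontal) and H596 (vertical), DOX over NO-DOX. Colors mark genes past an adjusted p of 0.05 in neither line, in H358, in H596 or in both. Genes called higher in both lines lie at the upper right, 14 called lower in both at the lower left, and 40 called in opposite directions at the other corners.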

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

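The tests of doxycycline itself, of 3 libraries left out, of a single library for the cornification genes, of the length and GC trend, and of splits of 1 line with the other left as it was, were chosen after the results were seen, as were the exact permutation of list means and the rank correlation over expressed genes in the splits.

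Differences between the lines that passed a test of the difference (H358 minus H596, log2) were found for 11 lists and 10 genes. The medians of the lists were 0.98 for glutathione and thioredoxin, 1.67 for detoxification and export, 0.65 for heme and iron, 1.27 for NADPH and pentose phosphate, 0.51 for cornification, 0.16 for proliferation and 0.39 for amino acid response genes. They were -0.53 for alveolar, -2.22 for interferon response, -0.99 for antigen presentation and -0.40 for fibroblast marker genes. The cornification list had a mean log2 CPM of only -0.47 with and -0.30 without DOX in H358, against 7.29 and 8.00 in H596. The fibroblast list was as low in H596, at -0.39 with and -0.31 without DOX. Where 1 line barely expresses a list, its difference need not be a difference in response. With an estimated correlation the glutathione and NADPH differences passed (adjusted p = 0.0388 each) and the other 9 did not. The genes were CYP4F11 (6.50), CYP4F3 (6.29), CMBL (5.86), AKR1B10 (5.64), TSPAN7 (4.48), KRT5 (-5.42), TRIM22 (-4.05), STEAP4 (-3.97), DSG3 (-3.82) and IL1R1 (-3.81).

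A tumor far from the others of its group was found in 4 groups of values, where chance alone gives about 1 in 20 of those examined, or 7.9. The antigen presentation mean was 4.54 log2 CPM in H358 DOX replicate 6, against 5.11 to 5.39 in the other 5. The Notch mean was 3.75 in H358 NO-DOX replicate 6, against 4.46 to 4.81, and TP63 in the same tumor was 6.47 CPM, against 29 to 39.6. KRT5 was 10.2 CPM in H358 DOX replicate 4, against 1.20 to 2.98. No explanation of these was tested.

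The fall of interferon response genes in H358 (median -1.49) was weighed first. With the stromal marker covariate the median was -2.15 (camera adjusted p = 4.77e-12), which argues against host reads that follow this marker mean. The mean pools genes of low level, 5 of them for macrophages and leukocytes, and its fibroblast part itself fell with DOX in H358. It can also hold reads of the tumor cells themselves. Reads from host cells, white blood cells above all, are therefore not excluded. In the main fit the list's camera call was lost with an estimated correlation (adjusted p = 0.125). The fall was not confined to 1 title number, with a median of -1.61 with number 7 and -1.38 with number 9. Each H358 group held 3 tumors of each number, so by design an even shift between the numbers could not have made it. Doxycycline itself stays open: in H596, on the same drug, the median was 0.37 (from 0.02 to 0.49 without any 1 library) and not called, but a line can respond to a drug in its own way, and no line without the NRF2 gene was analysed here. A lower interferon response with DOX in H358 may be the biological reading, as a hypothesis only.

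Opposite shifts of many genes in the lines were weighed second (rank correlation of the changes -0.27, jackknife SE 0.22, over 11946 genes). The changes followed transcript length with rho of -0.36 in H358 and 0.42 in H596, and with that trend and GC content removed the correlation was -0.11 (jackknife SE 0.19), which leaves open how much of it was length bias. Without any 1 library it ran from -0.346 to -0.165, so no single library accounts for it. Without 3 libraries together it was 0.038, and 38 of 100 splits of the samples, the real one included, gave a value as far from 0, with others from -0.632 to 0.720. Chance, or these 3 libraries together, may account for it, and no biological explanation was tested.

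The fall of cornification genes in H596 (median -0.79) was weighed last. The list means overlapped between the groups, with an exact permutation p of 0.115, so the spread between tumors may account for it. Without H596 NO-DOX replicate 1, which had 34.5% of its counts in its 50 most counted genes, the median was -0.43 (camera adjusted p = 0.000912), and with the length and GC trend removed it was -0.37 (camera adjusted p = 0.000990). Each of these takes away part of the fall and leaves a part, so neither could be excluded, and an effect of DOX or NRF2 stays untested against them.

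Other splits of the samples into groups of the same sizes were compared with the real one, 100 per result with the real one included. For the 2181 genes in H358, only the real split gave as many (highest other 210). Its share of 0.01 is the smallest that 100 splits can give, and it is unadjusted over the results compared this way. Not every possible split was drawn. The splits thus argue against chance for the H358 count but do not exclude it. For the 2187 genes that differ between the lines, 1 split of both lines gave as many (highest other 9), but most such splits called few or no genes in either line. With the other line left as it was, 3 splits of H358 and 4 of H596 gave as many, the real one included (highest other 2987 and 4489). These shares are under 0.05, unadjusted over the results compared this way, but other splits gave more genes than the real one. Splits of H596 alone gave a median of 447 genes, with the changes of H358 left in. The splits therefore do not exclude chance for this count, and it can also come from groups other than the treatment. For genes called higher in both lines, splits of both lines leave almost no genes to overlap and decide nothing, and with 1 line left as it was no other split gave as many (highest other 12 for H358 and 84 for H596). The 14 called lower in both were as many in 4 splits of H596 (highest other 25). For the 653 genes in H596, 4 splits gave as many, the highest other 3051. The 3 other splits that exceeded the real count all set H596 DOX replicate 2 with H596 NO-DOX replicates 1, 3 and 5, and their smaller groups held 4, 3 and 4 of the 5 NO-DOX tumors. They are near the real split with 1 or 2 tumors exchanged. The tumors set together, H596 DOX replicate 2 and H596 NO-DOX replicates 1, 3 and 5, had the lowest TMM factors of H596 (0.843, 0.516, 0.777 and 0.746, the next 0.916). They also had the fewest genes detected (18626, 17169, 18587 and 17693, the next 19031). These splits thus follow a difference between libraries, and whether it is apart from treatment was not tested. Called lists were as many in 19 splits for the 13 of H358 (highest other 17) and in 22 for the 9 of H596 (highest other 13), so the number of lists called by camera with its preset correlation was not beyond chance. The median number of lists called in the other splits was 8 in H358 and 7 in H596. The correlation of the changes between lines, 0.06, was as far from 0 in 28 splits (highest other 0.232).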

How the results depend on the processing

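The alternatives with 3 libraries left out, with sample quality weights and with the length and GC trend removed were chosen after the data were seen. Of 5188 repeats of 140 gene and list results, 4763 stayed on the same side of the threshold, 391 fell short of it, 32 newly passed and 2 turned direction with a call in either setting. Most alternatives left out 1 library, and a library of the other line reaches a result only through the shared fit. The pooled count thus mixes small and large alterations. With title number 9 alone 51 results fell short, with the replicate block 24 and with title number 7 alone 23. Of the 4763, 4558 kept direction, and 205 changed sign or test direction while called in neither setting. The 2 that turned with a call were the inflammatory cytokine genes of H596 with title number 9 (median -0.44, from 0.16) and the TSPAN7 difference on log2(TPM + 1) (-0.17, from 4.48). Counts of called genes beyond 1.5 times the reported 2181 (H358), 653 (H596) and 2187 (difference) were these. Title number 7 alone gave 1097, 178 and 573, and number 9 alone gave 294, 19 and 16, from fewer samples. No low-count filter gave 1447 differences, each line fitted alone about 1.6e+02 in H596, and the stromal marker covariate 1202 in H596. DESeq2 gave 1801 in H596 and 3297 differences, quality weights 5448 in H358, and an absolute log2 change of at least 1 gave 1121 in H358. Without the 3 libraries, H596 had 346 and 855 genes differed. Camera with an estimated correlation called 6 lists in H358 and 3 in H596, instead of 13 and 9. With the replicate number as a replicate block the counts were 1426, 141 and 543. Tumors of the same number correlated with r from -0.30 to 0.33 in H358 and from -0.26 to 0.25 in H596, so they were not taken as paired. Leaving out single libraries gave from 1553 to 2854 genes in H358, from 287 to 2069 in H596 and from 1335 to 3427 for the difference, from 12 to 15 and from 6 to 10 lists, and a correlation between lines from 0.02 to 0.10. For the difference, no fit of each line alone exists. Beyond fewer samples or genes, the cause was not tested. Depth limits genes near 0 counts, such as TSPAN7 in H358 NO-DOX with 1 count.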

Other observations

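Beyond the fixed lists, the genes that rose in both lines included several enzymes and membrane proteins, chosen here after their values were seen. PTGR1, a reductase of reactive aldehydes and prostaglandins, rose by 3.23 in H358 (adjusted p = 2.57e-11) and by 2.10 in H596 (adjusted p = 3.09e-07). The pannexin PANX2 rose by 3.30 and 2.87, the aspartyl hydroxylase ASPH by 2.22 and 2.26, and the ganglioside enzyme B4GALNT1 by 3.97 and 2.25. The mitochondrial cyclophilin PPIF rose by 2.81 and 1.87, and the growth factor EPGN by 3.60 and 2.22. NMRAL2P, a pseudogene whose reads can be shared with related genes, rose by 5.73 and 3.17. Of the genes called higher in both lines, which were 32.8% of the 381 called higher in H596, 74 had the larger change in H358.

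Genes that moved in opposite directions were also chosen after their values were seen. CYBRD1, an iron reductase, fell in H358 (-1.96, adjusted p = 1.44e-06) and rose in H596 (0.95, adjusted p = 0.0219), as did the mannosidase MAN1A1 (-1.46 and 2.39) and the bone and migration factor RUNX2 (-1.03 and 1.05). BOP1, a ribosome assembly protein, rose in H358 (1.02) and fell in H596 (-0.82). The number of genes called in opposite directions was 40, and it was 49 with the length and GC trend removed and 19 without 3 libraries.

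Some genes of 1 line could not be measured in the other. EPHB6, which fell in H596, had 0 counts in all H358 tumors. SLC34A2 had 1 count over the H596 DOX tumors and 0 over the NO-DOX tumors, and SCGB3A2 had 13 and 2, 10 of the 13 in DOX replicate 2 (edgeR adjusted p = 0.257). PIGR had 9 counts with DOX and 0 without in H596, 8 of the 9 in the same tumor (edgeR adjusted p = 0.286).

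Of 10 library measures compared within lines, after the data were seen, none passed adjustment. The number of genes detected was 20207 ± 950 in H596 DOX and 18599 ± 1296 in H596 NO-DOX (exact permutation p = 0.0455, adjusted p = 0.179). On the first principal component of H358, DOX replicates 4 and 5 lay at -89.9 and -76.7, and NO-DOX replicates 1 and 2 at 78.5 and 75.1. The 3 libraries left out together were these DOX tumors and H596 NO-DOX replicate 1, a choice made after the data were seen that left in the H358 tumors about as far out on the other side.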
